A study of Homo sapiens with 51 samples.

How the data were processed

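Gene expression was measured in 51 human breast cell lines with Affymetrix Human Genome U133 arrays (chip A), per the labels, with 1 array per line. The labels name the line of each array and give no other grouping. Each line was therefore its own group with n = 1, and no line could be tested against another. Lines whose names begin with HCC (14 lines), MDAMB (10 lines) and SUM (8 lines) were treated only as a possible batch, since shared names can mark a shared source laboratory. The other 19 lines have no such common name. Deposited values were used as the submitters gave them, 1 log2 intensity per probe set and array, running from 2.32 to 13.80. Which program summarised the probes into probe sets, and how background and differences between arrays were handled by the authors, is not given in the sources used here. Base 2 follows from the range, because natural logs of a 16-bit scanner signal end at 11.09. Array medians lay between 5.50 and 5.66, closer than the 0.5 log2 units that would have led to a shift, so no further normalization was applied. Without files from the scanner there are no detection calls, and low values could not be told from background. The number of arrays limits the precision of every value.

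The table held 22215 probe sets, of which 19065 were paired with 1 gene, 1043 with several genes and 2107 with none in the platform annotation. The probe sets without a pairing are unnamed here, which does not mean that they lack a gene. Symbols were updated through Entrez gene identifiers for 19053 probe sets with the RefSeq gene table of assembly GRCh38.p14, which also gave the order of genes along chromosomes. Its coordinates were not used. A gene was represented by the probe set with the highest mean over all arrays, and 4310 of the 11963 genes had several to choose from. Of the 103 list genes with several probe sets, 12 had another with an SD over 2 times that of the one used: AXL, BCL2, COL1A1, COL6A2, ESR1, GREB1, LOX, MTAP, RB1, SOX10, SPDEF and ZEB1. The ESR1 slopes were therefore also computed from the ESR1 probe set of highest SD, and the counts, correlations and list coherence from the most variable probe set of each gene. The calls of amplified regions, tumour suppressors and markers were not repeated in this way.

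Spread over lines was described with the SD and range of each gene. A gene or score was said to have separate low and high levels when an equal-variance normal mixture of 2 components had a BIC better by over 10 than 1 component, Ashman's D was over 2 and each component held at least 3 lines. For a pair, lines were split by the clusters of the first measure, or of the second where only that one had clusters, and correlations were computed within each cluster of at least 6 lines. Where both had clusters, those of the second were pooled. Slopes were fitted with the clusters of the measure as a term, and clusters of the responding gene were not modelled. Coherence of a gene list was its mean pairwise Pearson r, set against 10000 random lists of equal size matched on mean expression in 20 bins. Principal components used the 2000 genes of highest SD, centred. Correlations have Pearson's r and Spearman's rho with two-sided permutation p-values from 100000 permutations, 1e-05 being the smallest these can give. Each was repeated without the 2 lines farthest from the median of the first measure and within the 3 name series. Slopes of all genes on ESR1, on ERBB2 and on the mesenchymal and proliferation list scores were fitted with limma (lmFit and eBayes), leaving out the genes that make up the measure. A list score was the mean of its members' log2 values after centring each gene. Name series were compared with limma's F test. Correlation of genes adjacent on a chromosome was set against 1000 shuffled gene orders with a one-sided permutation p. Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. For the correlations the family was the relations computed, 30 from 20 gene pairs and 19 from 12 pairs of list scores, since a pair split into clusters gives more than 1 relation. These p-values measure consistency across lines and not the reproducibility of any line.

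Lists, pairs, tests and alternatives were chosen before the data were examined, apart from those named as later additions. There were 19 gene lists and 5 lists of markers of other cell types, with 238 genes, of which 211 were measured. Of 24 fixed gene pairs, 4 held a gene with no probe set of its own in the annotation. AR, TP53, TP63, KRT17, PTEN, BRCA2 and STAT1 are among the genes that could not be analysed for this reason. Genes named in the text are the 25 with the highest SD; in each list the 4 members of highest SD and, where it was coherent, the lines at its ends; the 10 genes of largest weight on each side of principal components 1 and 2; the 10 largest slopes each way in each fit; the genes of the fixed pairs; and in each amplified region the lines in which at least 3 members lay over 3 scaled median absolute deviations (MAD) above the median line. For the tumour suppressors, lines over 3 scaled MAD below the median were named. A line was described for the markers of another cell type when at least 3 markers lay over 3 scaled MAD and over 1 log2 unit above the median line. Other names were chosen after their values were seen, and the text says so there. Genes of the Y chromosome and XIST were never named.

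Alternatives were quantile normalization, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, leaving out the genes of lowest mean (7975 kept), leaving out AU565, LY2 and ZR75B, leaving out 4 lines of other or disputed origin (MCF10A, MCF12A, HBL100 and MDAMB435), the name series as a block, the array median as a covariate, the cluster term in or out, a stricter Ashman's D of 3, Spearman's rho for list coherence, the scaled MAD for the spread, and other gene sets for the principal components. Added after seeing the data were the most variable probe set of each gene, the ESR1 probe set of highest SD, leaving out each line in turn and removing array-wide trends from each gene. The procedures were tested on simulated data. With 200 of 11963 genes given a slope, the ESR1 fit recovered 11.9% of genes at a slope of 0.25, 46.3% at 0.5 and 78.8% at 1. In the ERBB2 fit these shares were 59.7%, 95.5% and 100%, in the mesenchymal fit 71.6%, 95.5% and 98.5%, and in the proliferation fit 26.9%, 64.2% and 92.4%. The mixture rule called 0 of 11963 simulated normal genes but 2200 of 11963 simulated right-skewed genes without levels, so it does not separate a high level from a long upper tail. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.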

Results

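Transcript levels of 11963 genes were compared across 51 established human breast cell lines. The panel holds lines from breast carcinomas and pleural effusions, the non-tumorigenic lines MCF10A and MCF12A, HBL100, and MDAMB435, whose breast origin is disputed. Its stated purpose is the study of functionally distinct breast cancer subtypes, but the labels assign no line to a subtype. There are no replicates, so all comparisons are between genes or gene groups over the lines. Levels are log2 intensities, and a difference of 1 is a doubling of signal.

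The genes that differed most between the lines encode secreted, structural and other proteins. SCGB2A2 (mammaglobin A, a protein secreted by breast epithelium) had the highest SD, 3.72, and ran from 2.71 in HCC70 to 13.09 in MDAMB415. KRT19, a keratin of simple epithelia, ran from 2.81 in MDAMB436 to 12.49 in BT483 with an SD of 3.46. The calcium-binding S100A8 and the trefoil factor TFF1, a classical oestrogen-induced gene, had SDs of 3.03 and 3.02. MAGEA6, a gene normally restricted to the testis, had an SD of 2.99 and reached 11.63 in MDAMB468. Cell adhesion and cytoskeleton genes were also among the 25 most variable. CDH1 (E-cadherin) lay between 2.69 in BT549 and 10.78 in BT483, VIM (vimentin) between 4.86 in AU565 and 12.99 in SUM1315, and CAV1 (caveolin) between 4.02 in ZR751 and 11.43 in HS578T. Across all genes the median SD was 0.40, 775 genes had an SD over 1 and 242 genes had a range over 6 log2 units. Of the 25 genes, 9 were also among the 25 of highest scaled MAD, a measure that gives little weight to a few extreme lines.

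Many of these genes took separate low and high levels. SCGB2A2 averaged 11.11 in 14 lines and 3.15 in the others, a difference of 7.96. KRT19 averaged 11.53 in 37 lines and 4.05 in the others. CDH1 was high in 35 lines (mean 9.46 against 3.79) and VIM in 18 lines (mean 11.28 against 6.03). Basal keratins were high in fewer lines, KRT14 in 9 (10.93 against 4.71) and KRT5 in 12 (10.35 against 5.28). The extracellular matrix genes COL1A2 and COL3A1 were each high in 4 lines, with means of 11.05 and 10.15. In total 994 genes (8.31%) met the mixture rule, among them 23 of the 25 most variable. The rule does not separate a high level from a long upper tail, and the count was 481 with the genes of lowest mean left out.

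Fixed gene lists varied together in 15 of 19 cases, with a mean pairwise r above that of random lists of like expression (permutation test, adjusted over the 19 lists). Interferon response genes had the highest mean pairwise r, 0.684, and their score ran from -1.32 in MCF10A to 3.23 in MDAMB468. MX1, an antiviral GTPase, averaged 9.71 in 10 lines and 5.27 in the rest, and IFI27 averaged 10.09 in 11 lines. Epithelial junction genes followed with 0.681, their score lowest in BT549 and highest in SUM225CWN. EPCAM, an epithelial adhesion molecule, was high in 41 lines (9.39 against 4.36), RAB25 in 39 and DSP (desmoplakin) in 40. Genes of the 8p11-12 region had 0.616, luminal differentiation genes 0.605 and basal genes 0.511. Lower values were found for the apocrine (0.479), cholesterol synthesis (0.477), proliferation (0.476) and mesenchymal lists (0.468). Of the 7 apocrine genes only 4 were measured, without AR. Among these, SCGB2A2 and SCGB1D2 had r of 0.865 and 0.876 with the rest of the list, ALOX15B 0.602 and PIP only 0.287. All 6 measured cholesterol synthesis genes, among them SQLE, HMGCS1, DHCR7 and INSIG1, were highest in SUM225CWN. Regions 17q12, 11q13 and 20q13 had 0.397, 0.361 and 0.307, oestrogen response genes 0.292 and hypoxia genes, with BNIP3, NDRG1, ADM and P4HA1 the most variable, 0.163. Of the oestrogen response genes, ESR1, GREB1 and BCL2 were read by probe sets of SD 0.39, 0.14 and 0.26. Other probe sets of these genes had SDs of 1.71, 1.83 and 0.60, so the value of 0.292 depends in part on the probe sets used. MHC class 2 genes passed narrowly (mean r 0.306, permutation adjusted p = 0.0457), with CD74 and HLA-DMA highest in HCC70 and HLA-DRA and HLA-DPA1 highest in MDAMB435. The tumour suppressor list (mean r 0.134, permutation adjusted p = 0.0521), TP53 targets (0.0969, permutation adjusted p = 0.0530), cancer-testis genes (0.113, permutation adjusted p = 0.299) and housekeeping genes (0.0670, permutation adjusted p = 0.135) did not pass. In the last list B2M, the light chain of MHC class 1, was at 3.47 in MDAMB157 and at 10.92 on average in the other 50 lines. MHC class 2 lost its call under 4 alternatives, and the hypoxia list lost its call without probe sets ending in _x_at or _s_at (mean r 0.0586). In the other direction, 4 recomputed values of lists that had not passed did pass under an alternative.

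The largest direction of variation had luminal and epithelial junction genes at one end and mesenchymal, basal and proliferation genes at the other. Principal component 1 held 21.2% of the variance of the 2000 most variable genes. At its positive end were KRT19, AGR2, SCGB2A2, TFF1, IGFBP5, GATA3, TFF3, ADIRF, CD24 and RHOB, and at its negative end CAV1, VIM, MSN, ANXA1, EMP3, TPM2, S100A2, SERPINE2, TGFBI and SPARC. All 12 luminal genes in the set had positive weights and all 12 mesenchymal genes negative weights, with mean weights at percentiles 100 and 0 of 10000 random lists. Epithelial junction genes were positive in 12 of 12 cases (percentile 100), basal genes negative in 9 of 11 (percentile 0.03) and proliferation genes negative in 6 of 6 (percentile 0.4). Along this component 25 lines lay at or below -1.47 and 26 lines at or above 9.18, with none between. Principal component 2 held 9.41% of the variance and had S100A8, LCN2, KRT5, S100A9, KRT7, KRT16, SLPI, S100P, KRT14 and RARRES1 at its positive end. All 11 basal genes, all 10 interferon genes and 11 of 12 epithelial junction genes in the set had positive weights on it, and all 10 oestrogen response genes negative weights. At its negative end were BASP1, GJA1, TFF1, SPARC, TUBA1A, CST3, RHOB, GNG11, CA12 and COL3A1. Scores on component 2 rose with the interquartile range of the array's values (r = 0.561, permutation p = 3e-05, adjusted p = 0.0006, rho = 0.454, permutation p = 0.00085, adjusted p = 0.00567, 20 relations, n = 51), and r was 0.553 without the 2 farthest lines.

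**Figure D1:**
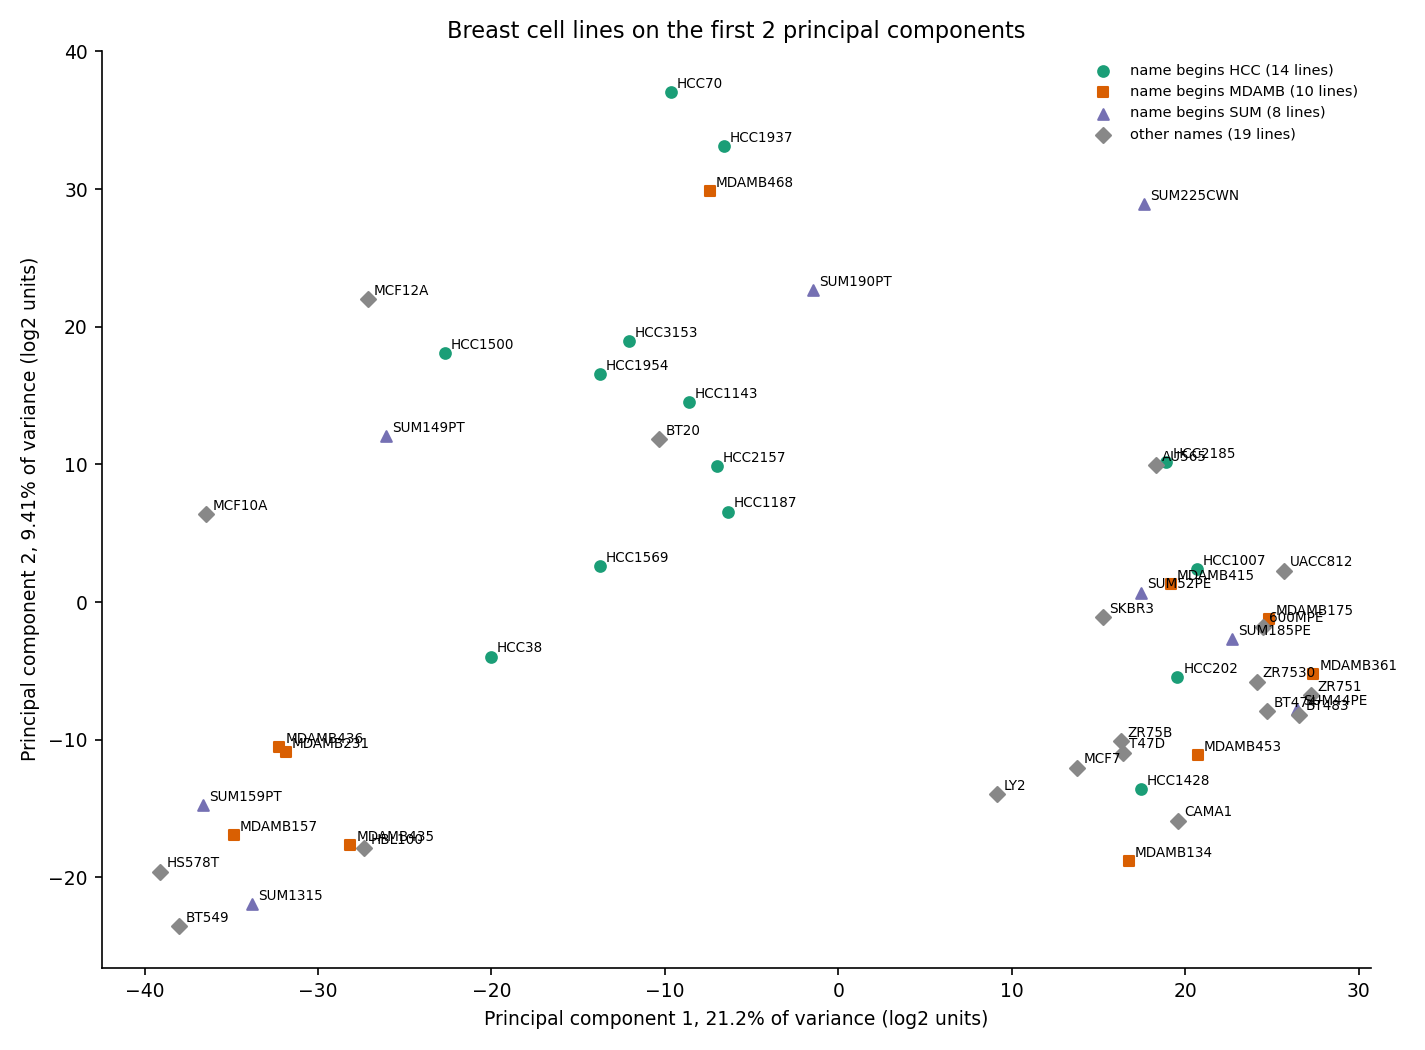
Scores of the 51 cell lines on principal component 1 (horizontal, 21.2% of variance) and principal component 2 (vertical, 9.41%), in log2 units, each point being 1 line with its name and the marker giving the beginning of the name. Lines of each name series lie on both sides of the gap along component 1, between -1.47 and 9.18.

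Correlations of fixed gene pairs asked whether genes with a shared lineage, region or pathway rise together. The luminal keratins KRT8 and KRT18, which form filaments with each other, had r = 0.888 (permutation p = 1e-05, adjusted p = 7.5e-05) and rho = 0.930 (permutation p = 1e-05, adjusted p = 6e-05) over 51 lines. Within the name series r was 0.901 (HCC), 0.971 (MDAMB) and 0.987 (SUM), and without the 2 farthest lines 0.842. FADD and PPFIA1, neighbours in 11q13, had r = 0.846 (permutation p = 1e-05, adjusted p = 7.5e-05) and rho = 0.821 (permutation p = 1e-05, adjusted p = 6e-05). Their r within series was 0.770, 0.915 and 0.783, and without the 2 farthest lines 0.796. LSM1 and ASH2L of 8p11-12 had r = 0.827 (permutation adjusted p = 7.5e-05) and rho = 0.799 (permutation adjusted p = 6e-05) in the 48 lines of lower ASH2L. Among the 18 lines with high VIM, those with more VIM had less CDH1 (r = -0.781, permutation p = 0.00012, adjusted p = 0.0006; rho = -0.814, permutation p = 0.0001, adjusted p = 0.000429), and r was -0.737 without the 2 farthest lines. These lines pool the low and high levels of CDH1, so a graded relation was not separated from a difference between the levels. In the 33 lines of low VIM r was 0.0224 (permutation adjusted p = 0.904). EGFR was lower where ESR1 was higher (r = -0.487, permutation p = 5e-05, adjusted p = 0.0003; rho = -0.544, permutation p = 5e-05, adjusted p = 0.00025), with r of -0.543, -0.49998 and -0.545 within the series and -0.524 without the 2 farthest lines. That r was -0.143 (permutation adjusted p = 0.402) without probe sets ending in _x_at or _s_at, which replaced the probe sets of both genes, and for EGFR left only ones with an SD of at most 0.22. ESR1 and GATA3 had r = 0.396 (permutation p = 0.00178, adjusted p = 0.00593) and rho = 0.419 (permutation p = 0.0023, adjusted p = 0.0069). ESR1 with FOXA1 did not pass in the lines of low or of high FOXA1 (r = -0.120 and 0.173, permutation adjusted p = 0.628 and 0.452). PGR, an oestrogen receptor target, followed ESR1 by rank (rho = 0.505, permutation p = 0.00016, adjusted p = 0.0006) while its r over all lines was 0.116 (permutation p = 0.324, adjusted p = 0.406) and within the HCC, MDAMB and SUM series 0.909, -0.0661 and 0.400. PGR was at 6.98 in T47D and averaged 3.56 in the other lines, so the rank relation is among low values, which could not be told from background. By the ESR1 probe set used, T47D itself had a level of 5.74, below the mean of 6.01. The ESR1 probe set of highest SD read 7.34 in T47D, on a range from 3.64 in SUM159PT to 10.31 in SUM44PE. In all these pairs ESR1 was read by a probe set that varied little (SD 0.39) and rose with the array median (r = 0.393, rho = 0.385).

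In all, 13 of 30 relations from 20 pairs passed by Pearson's r and 13 by Spearman's rho. GRB7 followed ERBB2 both in the 38 lines of low ERBB2 (r = 0.783, permutation adjusted p = 7.5e-05) and in the 13 of high ERBB2 (r = 0.828, permutation adjusted p = 0.00236), the latter missing the threshold by rho (0.571, permutation adjusted p = 0.0929). STARD3 did not pass in either cluster (permutation adjusted p = 0.843 and 0.125). Neither did ESR1 or EGFR in the clusters of ERBB2, nor ZEB1 with ESRP1 in the clusters of ESRP1. Relations within clusters leave out any difference between the low and the high cluster. CCND1 and CTTN had r = 0.471 overall (permutation adjusted p = 0.00259), but 0.0990, 0.787 and -0.0522 within the HCC, MDAMB and SUM series, and these differences between series were not past the threshold. KRT5 with KRT14 in the 39 lines of low KRT5 (r = 0.554), CAV1 with CAV2 in the 23 lines of high CAV1 (0.554) and FGFR1 with NSD3 in the 48 lines of lower NSD3 (0.341) also passed. ZEB1, a repressor of E-cadherin, had r = -0.435 with CDH1 in the 35 lines of high CDH1 (permutation adjusted p = 0.0229), which fell in size to -0.123 without 2 lines and rests on them. MKI67 with TOP2A did not pass (r = 0.295, permutation adjusted p = 0.0605; 0.147, 0.0751 and 0.936 within the HCC, MDAMB and SUM series). CDKN2A with MTAP did not pass either (r = 0.150, permutation adjusted p = 0.384; 0.177, 0.128 and -0.467 within the series), but the MTAP probe set used had an r of only -0.0265 with the most variable one of that gene. Without probe sets ending in _x_at or _s_at, which removes many of the pairs, 5 relations passed.

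Scores of whole gene programmes were related to each other as well. Luminal and mesenchymal scores ran in opposite directions over the 51 lines (r = -0.900, permutation p = 1e-05, adjusted p = 9.5e-05; rho = -0.853, permutation p = 1e-05, adjusted p = 6.3e-05). Within the HCC, MDAMB and SUM series r was -0.754, -0.888 and -0.960, and without the 2 farthest lines -0.881. Lines with higher luminal scores had lower proliferation scores (r = -0.652, permutation p = 1e-05, adjusted p = 9.5e-05; rho = -0.734, permutation p = 1e-05, adjusted p = 6.3e-05), within series -0.701, -0.661 and -0.748 and without the 2 farthest lines -0.684. Mesenchymal and proliferation scores rose together (r = 0.531, permutation p = 8e-05, adjusted p = 0.00038; rho = 0.619, permutation p = 1e-05, adjusted p = 6.3e-05), within series 0.319, 0.534 and 0.776 and without the 2 farthest lines 0.569. Luminal scores rose with oestrogen response in the 39 lines of low oestrogen response (r = 0.537, permutation adjusted p = 0.00163) and with the apocrine score in the 40 lines of low apocrine score (r = 0.580, permutation adjusted p = 0.000317). In the 11 lines of high basal score, more basal transcript went with less luminal transcript (r = -0.819, permutation adjusted p = 0.00231), but r was -0.575 (permutation adjusted p = 0.192) without the lines of other origin. Epithelial junction and mesenchymal scores in the 41 lines of high junction score had r = -0.374 (permutation adjusted p = 0.0452), which was -0.0681 without 2 lines and rests on them. Of 19 relations 7 passed by r and 6 by rho. Interferon with MHC class 2 scores (r = 0.123 and 0.406 in the clusters), hypoxia with proliferation (0.0249) and cholesterol synthesis with luminal scores (0.190) did not pass. With probe sets ending in _x_at or _s_at left out, 2 relations passed.

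Genes of regions known to be amplified in breast cancer were high together in some lines, from 10 lines for 17q12 to 1 line for 20q13. ERBB2, the receptor tyrosine kinase gene of 17q12, averaged 11.63 in 13 lines and 7.75 in the other 38. It was highest in SUM225CWN (12.99), where GRB7, PGAP3 and STARD3 lay 5.29, 5.13 and 3.56 above the median line. At least 3 members of the region were high in 10 lines, UACC812 with 8 of 11 members, BT474, AU565 and SKBR3 with 7, HCC1007, SUM190PT and HCC1954 with 4, and ZR7530, HCC202 and SUM225CWN with 3. ERBB2 itself varied too widely to be called high in any line by this rule, so these counts leave it out, and MDAMB361 (ERBB2 10.999) had only STARD3 and PGAP3 high. GSDMB was 5.37 above the median in AU565 and 5.04 in SKBR3. In 8p11-12, MDAMB134 and SUM44PE each had 9 of 12 members high, SUM52PE 6, BT483 5 and SUM225CWN 4. FGFR1, a growth factor receptor, was 4.96 above the median in MDAMB134 and 3.23 in SUM44PE, and RAB11FIP1 was 4.37 above it in SUM44PE. In 11q13, MDAMB134 had CCND1 (cyclin D1) 3.58 and PPFIA1 2.93 above the median, and MDAMB415 had CTTN, FADD and FGF4 high. In 20q13, BT474 had BCAS1, RAE1 and CSTF1 high, and PFDN4 was highest in MCF7 (10.34). Among the tumour suppressors only MTAP in SUM225CWN met the rule for a low level, 0.53 below the median. SMAD4 at 2.91 in MDAMB468 (mean over lines 4.63) and CDKN2A at 5.76 in MCF10A (mean 7.81, SD 1.37) did not meet it. The rule depends on the spread of each gene, so the lack of a call does not show that no line had a low level. CDKN2B averaged only 3.48, and low values could not be told from background. The probe sets used for MTAP and RB1 hardly varied (SD 0.21 and 0.26) and had r of -0.0265 and -0.0570 with the most variable ones of these genes, so low levels of either could have been missed and the MTAP call is uncertain. DNA copy number was not measured.

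**Figure D2:**
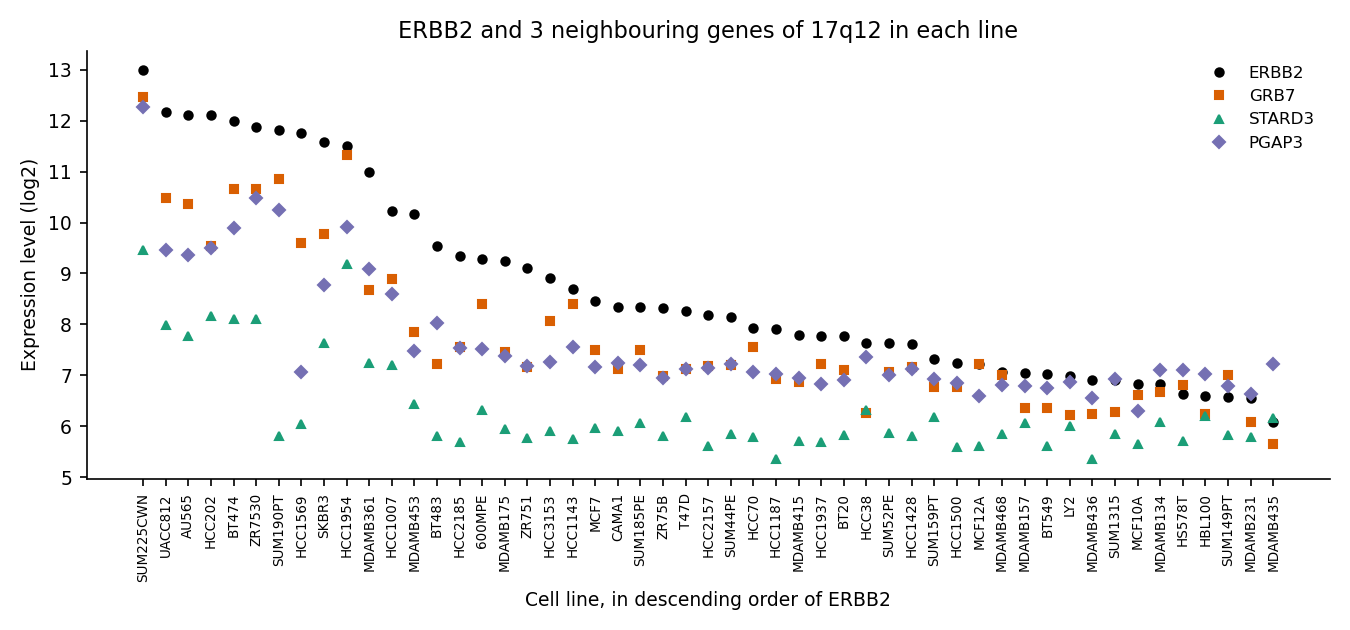
Expression levels (log2, vertical) of ERBB2, GRB7, STARD3 and PGAP3 in each of the 51 cell lines (horizontal, in descending order of ERBB2), with 1 point per gene and line. ERBB2 was highest in SUM225CWN at 12.99 and lowest in MDAMB435 at 6.08.

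ESR1 encodes the oestrogen receptor by which breast tumours are classed, and each gene's slope on its level was fitted over the 51 lines. Measured by the probe set of highest mean of its 9, ESR1 varied little (SD 0.39, highest in SUM44PE at 7.90). Per log2 unit of ESR1, TFF1 rose by 3.24 ± 0.985 (SE, limma adjusted p = 0.0324), RHOB by 2.97 ± 0.592 (adjusted p = 0.00165), IGFBP2 by 2.49 ± 0.545 (adjusted p = 0.00436) and GATA3, a luminal transcription factor, by 2.16 ± 0.701 (adjusted p = 0.0414). UCP2, CLU, NPY1R, SELENOP, CA12 and CEP15 had the next largest positive slopes, from 2.12 to 1.89. ANXA1 (-3.36 ± 0.861, adjusted p = 0.0140), S100A2 (-3.04 ± 0.762, adjusted p = 0.0120) and the basal keratin KRT5 (-2.89 ± 0.729, adjusted p = 0.0128) had the most negative slopes, followed by PLS3, CAV1, MSN, EGFR, PRNP, TGFBI and IFI16. By list, 6 of 13 oestrogen response genes rose and none fell (7 adjusted over the list alone), 3 of 12 luminal genes rose (5 adjusted over the list alone), and 6 of 12 genes of 8p11-12 rose (11 adjusted over the list alone), among them LSM1 and ASH2L. SUM44PE, the line of highest ESR1, also had 9 of the 12 genes of 8p11-12 high, and how far their rise rests on it was not tested. Of 11 basal genes 3 fell (6 adjusted over the list alone), as did 4 of 17 mesenchymal and 5 of 17 proliferation genes (4 and 11 adjusted over the list alone). In the other lists at most 1 member passed. Of the 20 slopes named here, 14 no longer passed with the array median as a covariate, 12 without the lines of other origin and 8 after quantile normalization.

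In total 1141 of 11962 genes passed in the ESR1 fit, 755 with positive and 386 with negative slopes, and none of 100 shuffles of the ESR1 values gave as many (highest 235). This count moved with the scaling of the arrays and with the lines included. ESR1 by this probe set rose with the array median (r = 0.393, permutation p = 0.00462, adjusted p = 0.0132, rho = 0.385, permutation p = 0.00565, adjusted p = 0.0188, r = 0.390 without the 2 farthest lines). It fell with the array interquartile range (r = -0.445, permutation p = 0.002, adjusted p = 0.008, rho = -0.408, permutation p = 0.00325, adjusted p = 0.013), which was not used as a covariate. With the array median as a covariate 110 genes passed, 88 positive and 22 negative. After quantile normalization 418 passed, and 301 without the 4 lines of other origin. The count was 482 without MCF12A, 614 without HCC70, 640 without HCC202, 667 without MCF10A and 2757 without SUM44PE. The ESR1 probe set of highest SD, chosen after its values were seen, had an SD of 1.71 and was highest in SUM44PE (10.31), MDAMB134 (9.77) and BT483 (9.53). It had no such relation to the array median (r = 0.169, permutation p = 0.237, adjusted p = 0.339; rho = 0.0401, permutation p = 0.780, adjusted p = 0.905; r = 0.193 without the 2 farthest lines). With it 1222 genes passed, 672 positive and 550 negative, and 1096 with the array median as a covariate. Left out in turn, no line moved this count outside 1019 to 1382. TFF1 (1.19 ± 0.183 per log2 unit, limma adjusted p = 2.08e-05), GATA3 (0.85 ± 0.127, adjusted p = 1.47e-05) and IGFBP2 (0.81 ± 0.0934, adjusted p = 4.30e-08) were again among the largest positive slopes and ANXA1 (-1.04 ± 0.170, adjusted p = 4.41e-05) the most negative. With this probe set 11 of 12 luminal genes, 9 of 13 oestrogen response genes and 9 of 12 genes of 8p11-12 rose. SUM44PE, MDAMB134 and BT483, the lines of highest ESR1, also had 9, 9 and 5 of the 12 genes of 8p11-12 high. How far the rise of this region rests on these few lines was not tested. Both probe sets called 363 genes, with the same sign in each, but the fits share all arrays and gene values and the probe sets are correlated (r = 0.624), so no expected number can be set beside this.

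ERBB2, another receptor by which breast tumours are classed, rose together with epithelial junction genes once the difference between its low and high clusters was set aside. Its slopes were fitted with the cluster as a term, as 1 slope common to the 38 lines of low and the 13 lines of high ERBB2, and the clusters were not tested separately. Per log2 unit, KRT19 rose by 2.14 ± 0.460 (limma adjusted p = 0.00334), S100P by 1.49 ± 0.364 (adjusted p = 0.00900) and CD24 by 1.45 ± 0.260 (adjusted p = 0.000562). TFF1, IGFBP5, CDH1, AGR2, RAB25, AZGP1 and TFF3 were the others of the 10 largest. The most negative slopes belonged to CAV1 (-1.40 ± 0.353, adjusted p = 0.0112), VIM (-1.38 ± 0.386, adjusted p = 0.0219) and EMP3 (-1.35 ± 0.248, adjusted p = 0.000692), followed by DKK1, GPX1, SERPINE2, MSN, TGFBI, NT5E and BAG2. Of the epithelial junction genes 12 of 13 rose (13 adjusted over the list alone), of the luminal genes 9 of 12 (12 adjusted over the list alone), and 7 of 17 mesenchymal genes fell (13 adjusted over the list alone). In the 17q12 region 2 of 10 genes rose, GRB7 (0.67 ± 0.0871, limma adjusted p = 6.60e-06) and PGAP3 (0.42 ± 0.0973, adjusted p = 0.00601), and the same number adjusted over the list alone. In total 721 of 11962 genes passed, 379 positive and 342 negative, and 0 of 100 shuffles gave as many (highest 1). Without the 4 lines of other origin 373 genes passed, and 9 of the 20 named slopes did not.

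Along the mesenchymal score, luminal and junction genes fell as a body while matrix and stromal genes rose. All 12 luminal genes and all 13 epithelial junction genes fell, in the fit over all genes and adjusted over the list alone. KRT19 fell by 2.37 per unit of score (SE 0.260, limma adjusted p = 1.29e-09) and AGR2 by 1.79 (SE 0.217, adjusted p = 1.53e-08). TFF1, IGFBP5, SCGB2A2, GATA3, EPCAM, CD24, KRT8 and RAB25 followed. ANXA1 rose by 1.71 ± 0.231 (adjusted p = 1.98e-07), EMP3 by 1.57 ± 0.121 (adjusted p = 8.94e-14) and TPM2 by 1.55 ± 0.170 (adjusted p = 1.29e-09), followed by SERPINE2, NNMT, LDHB, S100A2, FABP5, LGALS1 and ANPEP. All 7 stromal fibroblast markers rose (7 adjusted over the list alone), COL3A1 by 0.95 ± 0.164 and LUM by 0.75 ± 0.132. COL3A1 and LUM were each high in only 4 lines (means 10.15 and 7.67, against 4.02 and 2.74 in the others). Those lines were all among the 5 of highest mesenchymal score, so these slopes need not be a graded rise over the panel. The score itself includes matrix genes such as COL1A2 and SPARC. Of the proliferation genes 8 of 17 rose (11 adjusted over the list alone), among them CDC20 and TYMS, and of the oestrogen response genes 5 of 14 fell (6 adjusted over the list alone). In total 2212 of 11946 genes passed, 1104 positive and 1108 negative, against at most 6 in 100 shuffles. The mixture rule did not split this score, but with a term for its 12 highest lines 433 genes passed, and 9 of the 20 named slopes did not.

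The proliferation score, built from cell cycle genes and itself higher in lines with a lower array median (r = -0.395, permutation p = 0.00458, adjusted p = 0.0132; rho = -0.434, permutation p = 0.0016, adjusted p = 0.008; r = -0.352 without the 2 farthest lines), was highest in MDAMB231 (0.73) and lowest in SUM185PE (-1.77), where CDC20, TYMS and RRM2 were lowest of all lines. AURKA was lowest in SUM44PE. Of the basal genes 4 of 11 rose with the score (5 adjusted over the list alone). The largest positive slopes over all genes were those of CAV1, by 3.36 ± 0.595 per unit (limma adjusted p = 5.71e-05), MSN by 3.28 ± 0.511 (adjusted p = 6.89e-06) and VIM by 2.80 ± 0.673 (adjusted p = 0.00227), followed by FABP5, TUBB6, PLS3, S100A2, TGFBI, IFI16 and EGFR. The most negative slopes were those of KRT19, which fell by 3.78 (SE 0.815, adjusted p = 0.000698), AGR2 by 3.48 (SE 0.591, adjusted p = 2.92e-05) and SCGB2A2 by 3.44 (SE 0.927, adjusted p = 0.00640). SLC2A10, IGFBP5, TFF3, TFF1, GATA3, PIP and SELENOP followed. Of the luminal genes 9 of 12 and of the junction genes 9 of 13 fell (11 and 12 adjusted over the list alone), and 7 of 17 mesenchymal genes rose (8 adjusted over the list alone). In total 2063 of 11946 genes passed, 1079 positive and 984 negative, against at most 3 in 100 shuffles. With the array median as a covariate 1449 passed, 697 positive and 752 negative. Without probe sets ending in _x_at or _s_at 1052 genes passed of 8356 tested.

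Genes lying next to each other on a chromosome varied together across the lines. Adjacent genes had a mean r of 0.179 over 11908 pairs (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give), with 73.0% of pairs above 0. Shuffled gene orders averaged 0.0157 and reached 0.0223 at most. Without pairs whose symbols share their first 3 letters the mean was 0.169, and it fell with distance, to 0.105 for genes 10 places apart and 0.0537 for genes 100 places apart. Windows of 10 genes, named after their values were seen, reached a mean pairwise r of 0.546 on chromosome 17 from DHX40 to BCAS3, a stretch that holds RPS6KB1 and PPM1D and averaged 2.45 above its mean over lines in MCF7. The window from MRPL58 to MRPS7 on the same chromosome had 0.540 and was highest in MDAMB453. The next held immune receptor genes of the LILR and KIR families on chromosome 19 (0.536, highest in HCC202 by only 0.27), and families in tandem also made up windows of metallothionein (0.499), PSG (0.469), histone (0.461) and protocadherin genes (0.453). On chromosome 8 the window from EIF4EBP1 to PLEKHA2 with FGFR1 had 0.451 and was highest in MDAMB134 (1.99). On chromosome 4 the window from CTBP1 to FAM193A with FGFR3 was highest in SUM185PE (1.82). Over all 11724 windows the median was 0.124. Gene order is that of assembly GRCh38.p14.

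**Figure D3:**
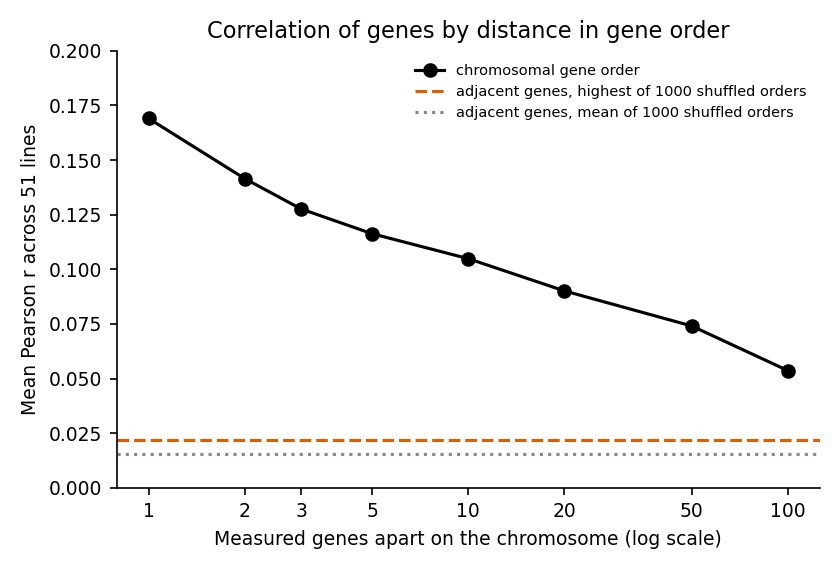
Mean Pearson r across 51 lines (vertical) of pairs of measured genes by the number of places between them on the chromosome (horizontal, log scale), without pairs whose symbols share their first 3 letters. The mean fell from 0.169 for adjacent genes to 0.0537 at 100 places, while the dashed line is the highest (0.0220) and the dotted line the mean (0.0157) of 1000 shuffled orders.

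Markers of other cell types set MDAMB435 and 4 mesenchymal lines apart. In MDAMB435, 6 of 7 melanocytic markers were high. The pigment enzymes TYRP1 and TYR reached 9.66 and 9.12, or 6.03 and 3.81 above the median line, the melanosome protein gene MLANA 9.88 and the transcription factor gene MITF 8.41. The same line had little KRT19 (3.10), EPCAM (4.27) and CDH1 (4.25) and much VIM (12.56). Stromal fibroblast markers were high in 4 of 7 cases in SUM1315, HS578T, BT549 and MDAMB157. COL3A1 was 7.54 above the median in MDAMB157 and 7.08 in BT549, THY1 3.69 above it in HS578T, and LUM 6.38 above it in BT549 and 5.24 in SUM1315. No line had 3 high leukocyte, endothelial or erythroid markers, the most being 2 of 6, 1 of 5 and 0 of 2.

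**Figure D4:**
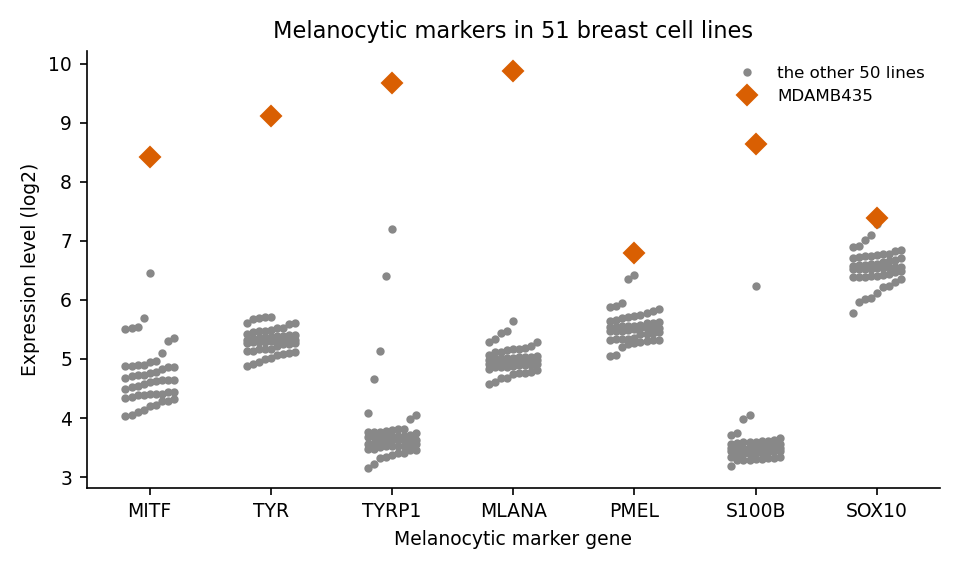
Expression levels (log2, vertical) of 7 melanocytic marker genes (horizontal) in the 51 cell lines, with 1 point per line, spread sideways for visibility, and MDAMB435 as a diamond. MDAMB435 had the highest level of each of MITF (8.41), TYR (9.12), TYRP1 (9.66), MLANA (9.88), PMEL (6.80) and S100B (8.65).

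Lines known to derive from a common source were each other's closest line in all 3 pairs. Over genes centred across lines, AU565 and SKBR3 had r = 0.612 and MCF7 and its derivative LY2 r = 0.562, ranks 2 and 3 of 1275 pairs of lines. ZR751 and ZR75B had r = 0.337, rank 37. These correlations are across genes, which are not independent replicates. Set beside them, MCF10A and MCF12A, established separately but alike in name and non-tumorigenic, had the highest r of all pairs (0.674). ZR751 and ZR7530 had 0.292. The median r over all pairs was -0.0401. The arrays of MCF12A and MCF10A had the lowest medians of all lines (5.50 and 5.52) and the widest interquartile ranges (2.82 and 2.78). How far these array-wide values contribute to the r of MCF10A with MCF12A was not tested.

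Lines of the HCC, MDAMB and SUM name series did not differ in any gene after adjustment. Among 11963 genes, 0 passed limma's F test at the adjusted threshold and 892 had an unadjusted p under 0.05. The closest were TCF7L1, with means of 7.16 ± 0.81 (SD, n = 14), 5.96 ± 0.65 (n = 10) and 5.64 ± 0.36 (n = 8) in the HCC, MDAMB and SUM lines (limma adjusted p = 0.0745), and RPLP2 (adjusted p = 0.0745), both chosen after their values were seen. In simulated data of this size only the SUM lines were shifted, in 200 of 11963 genes. There the test found 71% of differences of 1 log2 unit and 95% of differences of 2, with 15 false calls. These shares hold for that setting and not for a few shifted genes or another series. With the most variable probe set of each gene 4 genes passed.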

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

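Among the alternatives, the most variable probe set of each gene, the ESR1 probe set of highest SD, leaving out single lines and removing array trends were chosen after seeing the data, the last before its own result was seen. Of the recomputed counts and main values 96 stayed within their limits and 16 moved, most of them being counts, which have no direction. Leaving out each line in turn is not in these totals, apart from the ESR1 fit without SUM44PE. Of the recomputed correlations 259 kept their call, 8 lost it, 6 gained it and 11 changed sign without passing in either setting. For list coherence 122 values kept their call, 5 lost it, 4 gained it and 1 changed sign without passing in either setting. No correlation or list that had passed changed sign. The most variable genes, those with an SD over 1 (775), were 505 by scaled MAD and 483 without _x_at and _s_at probe sets, where fewer genes were tested. Of the principal components, the first held 17.002% with all genes and 17.7% with genes scaled to unit variance. Without _x_at and _s_at probe sets 5 gene relations and 2 list relations passed, and 1052 of 8356 genes passed with proliferation, against 2063 of 11946. Genes with separate levels were 481 of 7975 without the genes of lowest mean, against 994 of 11963 (8.31%). With ESR1 (1141 of 11962 genes) 721 of 8368 passed without _x_at and _s_at probe sets, a setting that also replaced the ESR1 probe set by that of highest SD. With the main probe set the count was 110 with the array median as a covariate, 418 after quantile normalization and 301 without lines of other origin. Leaving out each line in turn gave 482 (without MCF12A) to 2757 (without SUM44PE), and also 614 without HCC70, 640 without HCC202 and 667 without MCF10A. With ERBB2 (721) the count was 373 without lines of other origin and 555 to 939 leaving out each line. With the mesenchymal score (2212) it was 433 with the cluster term and 2054 to 2277 leaving out each line, and with proliferation (2063) 1771 to 2431. Between the name series 4 genes passed with the most variable probe set of each gene and 0 otherwise. Of the recomputed named slopes 717 kept their call and 81 lost it, with ESR1 14 of 20 lost under the array median, 12 without lines of other origin and 8 after quantile normalization. With ERBB2 9 of 20 were lost without lines of other origin, 8 without the cluster term and 6 with the mean of probe sets, and with the mesenchymal score 9 of 20 with the cluster term. The cause of these shifts was not tested, apart from array-wide signal for ESR1. No paired analysis was possible because the labels give no groups and 1 array per line. ERBB2 has no probe set without the _x_at or _s_at ending, ESR1 by its probe set of highest mean has an upper component of 1 line, and similarity of sister lines needs those lines, so these 3 alternatives were not run. By its probe set of highest SD, ESR1 had components of 18 and 33 lines but missed the mixture rule (BIC gain 9.05). No fit with that split as a term was run.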

Other observations

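Some lines held levels of single genes or programmes far from the rest. HCC1569 was among the 13 lines of high ERBB2 (11.76), but its STARD3 (6.04) and PGAP3 (7.07), neighbours of ERBB2, lay near the median line (5.90 and 7.14). SUM225CWN had the highest ERBB2, GRB7, STARD3 and PGAP3 of the 51 lines and also the highest levels of all 6 cholesterol synthesis genes measured, a list not related to the region. CD14, a monocyte receptor, reached 8.94 in HCC70 against a median of 4.52, and CDH5, an endothelial cadherin, 7.12 in BT20 against 3.36, without 3 high markers of either cell type. PDGFRB stood at 8.23 in MDAMB157 against 5.68. TP53I3, a target of p53, reached 11.94 in T47D. These genes and lines were chosen after their values were seen.

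The ESR1 count with the array median as a covariate and the comparison of the name series were planned, and the test of array trends among neighbouring genes was chosen after the data were seen but before its own result. The other tests, and the reading of the planned ESR1 count as a test of array-wide signal, were chosen only after the result was seen. Neighbouring genes varied together (mean r 0.179 against at most 0.0223 in shuffled orders). Gene families in tandem, as the whole cause, were argued against by a mean r of 0.169 without pairs sharing 3 letters, and overlapping transcripts by 0.116 for genes 5 places apart. Array-wide signal acting on dim genes, as the whole cause, was argued against by 0.2715 among brighter genes after the array trends were removed (0.261 as measured). That test left out the dimmer genes, so how far such signal adds to the mean r of 0.179 over all genes was not tested. DNA copy number stays open, since it was not measured, and no biological explanation was tested.

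In MDAMB435, 6 of 7 melanocytic markers were high. Melanocytic cells mixed into a mainly epithelial culture were argued against by the epithelial junction genes, whose median lay at -2.71 from the median line (range -4.98 to -0.60). A mislabelled sample cannot be told apart from a property of the line, since there is no second array of it. The number of other lines with 3 high melanocytic markers, 0, would be the same after an exchange of labels and decides nothing. The breast origin of this line is disputed, which was not tested here.

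The number of genes following ESR1 moved with the processing. Array-wide signal read by the probe set of highest mean is a candidate explanation, as 1141 genes became 110 with the array median as a covariate. For the ESR1 probe set of highest SD the same test argued against it, with 1096 genes left of 1222. No biological explanation was tested.

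The HCC, MDAMB and SUM series gave 0 genes by limma's F test (892 at an unadjusted p under 0.05), and the highest count of the other splits of the same lines was 1. Since any split gives at least 0 genes, 100 of 100 gave as many by construction, and the splits decide nothing about chance. Among 13 relations compared between the series none differed in r, the lowest permutation adjusted p being 0.522.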
